A study of Mus musculus with 6 samples.

How the data were processed

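The series holds sorted splenic γδ T cells of 6 mice, 3 healthy (day 0) and 3 at day 7 of infection with Mycobacterium abscessus, each numbered as a separate mouse in the labels. Per the labels' protocols, RNA was reverse transcribed with an anchor sequence, and γ and δ chain amplicons were sequenced on an Illumina MiSeq. The same labels describe bulk RNA sequencing of these cells, which was not analysed here. Each mouse had 1 table of γ clones and 1 table of clones from the shared α and δ locus, 12 tables in all.

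Per the file headers, each clone had a deposited count of unique molecules and a deposited count of reads, and the authors' fraction of each within its table. Both counts were whole numbers without normalization, and the deposited fractions summed to 1 within a table and were not used further. Clones were keyed on the nucleotides of the CDR3 with V, D, J and C segments, per the file headers, and no clone had under 4 reads. The tool that called the clones, its version and its treatment of errors in the molecular identifiers are not given in the sources used here. GRCm38 is the build named in the submitters' processing notes, and coordinates are those of the same build's annotation.

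Molecules were the main weight and reads an alternative. Delta chains were the clones with a TRDJ segment. Productive clones, those without a stop codon or frame shift in the CDR3, entered the comparisons, and a clonotype was a V segment, a J segment and a CDR3 amino acid sequence. The first V segment listed was used. Nonproductive clones made up 31.0% ± 3.99 (SD, n = 3) of γ molecules in healthy and 16.3% ± 0.561 in infected libraries, and 2.93% ± 0.265 and 0.421% ± 0.0739 of δ molecules. Between 72.4 and 80.0% of γ clones and between 79.9 and 92.1% of δ clones had 1 molecule. Reads per library ranged from 16789 to 45468 for γ and from 40640 to 92948 for δ. Libraries of the same group shared 21.9 to 31.6% of their γ nucleotide clonotypes and 1.67 to 5.24% of their δ ones, so no library was counted as a copy of another.

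Counts per V segment, J segment, V-J pair and clonotype were compared with edgeR 4.0.16 in R 4.3.3, using glmQLFit and glmQLFTest with group as the only term, all 6 libraries, and the library's productive total as its size without further scaling. V-J pairs and clonotypes needed at least 10 molecules in at least 3 libraries, and segments had no filter. P-values were adjusted within each table by the Benjamini-Hochberg method, with a threshold of 0.05. The standard errors printed beside log2 changes come from the log2 shares per library with 0.5 added to each count. Shares of single libraries have exact Clopper-Pearson 95% intervals. Shares, diversity, overlap and CDR3 length were compared by two-sided exact permutation tests of group means (one-sided for pairs within against across groups), for which 3 against 3 libraries give no p under 0.1. Diversity was the mean over 100 seeded draws of the smallest library's productive total, 373 molecules for γ and 1550 for δ, and 324 and 799 without the canonical chains. Clonality was 1 minus the Shannon entropy over the logarithm of the number of clonotypes. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

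The tests, the alternatives and the rule for named items were chosen before the data were examined, except where the text says otherwise. The rule named every TRGV, TRGJ and TRDJ segment, TRDV segments with a mean share of at least 1% in either group or past the threshold, up to 10 V-J pairs and 5 clonotypes per direction past the threshold, the 3 largest pairs and clonotypes of each group, the largest clonotype of each library, and a fixed list. That list held the invariant Vγ6 or Vγ5 chain, the Vδ1 chain, the Vδ5 chain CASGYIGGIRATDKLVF, the Vδ6 family (TRAV15 with DV6, the D and N copies included), the invariant NKT and MAIT α chains, any other α rearrangement and immunoglobulin segments. Chains named only from the repertoire without the canonical chains were chosen after their values were seen.

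The alternatives chosen then were TMM factors, DESeq2 1.42.0 with its size factors, a replicate block, leaving out each library, leaving out clones of 1 molecule, counting each clonotype once, adding nonproductive clones, no filter or 50 molecules in 3 libraries, CDR3 nucleotides or amino acids alone, the δ chain by its C segment, near-identical V segments summed, full depth and the Jaccard index. Reads in place of molecules, every comparison without the canonical chains and the scaling of the Vδ6 family were added after the data were seen.

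The count test was tested on simulated counts, drawn from the shares of the healthy libraries and the totals of all 6. Variation between libraries was set and not estimated from the data. Known features were raised without lowering the others, so the large shift in shares seen here was not simulated. Unchanged features were called in up to 7.5% of cases, for TRDJ segments. The test recovered 80% of 2-fold and 100% of 4-fold changes for the 6 TRGV segments, 27.5 and 47.5% for the 47 TRDV segments, 80 and 97.5% for the 4 TRGJ segments and 100% of each for the 2 TRDJ segments. It recovered 67.5 and 100% for the 8 γ and 95 and 100% for the 13 δ V-J pairs, and 55 and 100% for the 7 γ and 60 and 100% for the 3 δ clonotypes. It recovered 0% of either fold for the 5654 δ clonotypes without a filter.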

Results

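T cell receptor γ and δ chains were sequenced as amplicons from sorted splenic γδ T cells of 3 healthy mice and of 3 mice at day 7 of infection with Mycobacterium abscessus, a rapidly growing non-tuberculous mycobacterium. The comparison of the 6 libraries addresses how the diversity of receptor clonotypes goes with the γδ T cell response to this infection. Each library had 1 table of γ clones and 1 table of δ clones, with reads collapsed to molecules by unique molecular identifiers. The γ tables held 570 to 892 molecules in healthy libraries and 1899 to 2728 in infected ones, and those of δ clones held 1595 to 1867 and 7777 to 10399. The mean number of molecules was thus 3.01 times as high after infection for γ and 5.11 times for δ (two-sided exact permutation test, p = 0.1 for each, the smallest p that 3 against 3 libraries can give). The number of γ clones was 434 ± 74.3 (SD, n = 3) in healthy and 435 ± 60.9 in infected libraries (exact permutation p = 1), and the number of δ clones was 1237 ± 180 and 828 ± 178 (exact permutation p = 0.1). Productive chains only, 373 to 2268 molecules per library for γ and 1550 to 10362 for δ, entered the comparisons that follow.

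After infection 1 γ chain and 1 δ chain, both invariant and both known from Vγ6 Vδ1 cells, took most of the repertoire. The Vγ6 chain joins TRGV6 to TRGJ1 with the CDR3 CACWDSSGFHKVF, and the Vδ1 chain joins TRDV4 to TRDJ2 with the CDR3 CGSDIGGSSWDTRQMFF. Cells with this receptor arise in the fetal thymus, settle in tissues and are known to make IL-17. The Vγ6 chain made up 13.8% ± 0.799 (SD, n = 3) of productive γ molecules in healthy libraries and 74.5% ± 2.27 in infected ones, a 5.42-fold rise (log2 2.43, SE 0.05). The Vδ1 chain rose 5.25-fold, from 16.7% ± 2.36 to 87.8% ± 4.24 of productive δ molecules (log2 2.39, SE 0.12). In molecules, the Vγ6 chain went from 49 to 85 per healthy library to 1229 to 1686 per infected library, and the Vδ1 chain from 265 to 301 to 6414 to 9331. The molecules were copied from RNA, and receptor transcripts per cell were not measured. The number of cells behind each library is not given in the sources used here either, so molecule counts cannot be read as cell counts. All other productive molecules together numbered 449 ± 109 and 484 ± 106 for γ (exact permutation p = 0.6) and 1402 ± 148 and 1051 ± 263 for δ (exact permutation p = 0.2).

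Both rises passed edgeR's quasi-likelihood test among the clonotypes tested (adjusted p = 2.28e-23 for γ, adjusted p = 1.95e-09 for δ), and both held in 3 of 3 infected libraries against every healthy one. The exact permutation p of the shares was 0.1 for each chain. TRDV4 with TRDJ2 had an edgeR adjusted p = 2.00e-19 among δ V-J pairs, so the size of such p-values depended on the features tested together. The lowest infected share was 72.3% for the Vγ6 chain (exact Clopper-Pearson 95% interval 70.2 to 74.3%) and 82.9% for the Vδ1 chain (82.0 to 83.7%). The highest healthy shares were 14.7% (11.9 to 17.8%) and 19.4% (17.5 to 21.5%), and these intervals cover counting error only. Weighted by reads, the shares went from 16.9% ± 3.76 to 59.8% ± 2.88 for the Vγ6 chain and from 11.5% ± 1.23 to 71.6% ± 8.86 for the Vδ1 chain. With TMM scaling of the 3 δ clonotypes tested, the log2 change of the Vδ1 chain was 0.074 and did not pass. Each chain was encoded by a single nucleotide sequence in all 6 libraries, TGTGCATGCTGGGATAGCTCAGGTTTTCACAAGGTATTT for Vγ6 (4435 molecules) and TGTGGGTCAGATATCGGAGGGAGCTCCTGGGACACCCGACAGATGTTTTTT for Vδ1 (24104 molecules). On GRCm38, TRGV6 lies on chromosome 13 at 19190356 to 19190929 and TRGJ1 at 19210343 to 19210402, both on the plus strand. TRDV4 lies on chromosome 14 at 54074905 to 54075515 and TRDJ2 at 54136779 to 54136837, also on the plus strand. All are annotated as V or J gene segments of a T cell receptor.

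**Figure D1:**
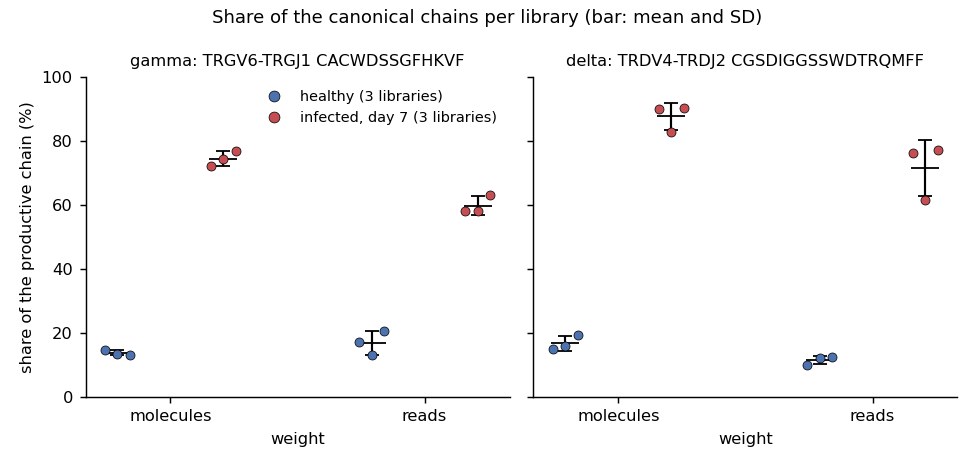
Share of productive γ molecules or reads taken by the Vγ6 chain and of productive δ molecules or reads taken by the Vδ1 chain (y axis, percent), with 1 point per library and bars for the mean and SD of 3 healthy and 3 infected libraries. By molecules, infected libraries lay between 72.3 and 76.8% for γ and between 82.9 and 90.4% for δ, above healthy libraries at 13.1 to 14.7% and 14.98 to 19.4%.

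Among γ segments, the rise of the Vγ6 chain went with a lower share of TRGV1, the main γ segment of the resting spleen. TRGV6 rose from 15.01% ± 0.910 to 74.7% ± 2.33 of γ molecules (n = 3, log2 2.32), while TRGV1 fell from 59.6% ± 1.498 to 15.5% ± 1.24 (log2 −1.94) and TRGV3 from 7.16% ± 1.02 to 1.81% ± 0.0783 (log2 −1.95). The TRGV1 shares here and below may hold TRGV2 chains, since TRGV1 is 95.2% identical to TRGV2, no clone was listed with TRGV2, and 44.4 to 58.7% of TRGV1 molecules per library were joined to TRGJ2, the usual partner of TRGV2. TRGV3 is 94.9% identical to TRGV1 and 94.3% to TRGV2. Of 110 healthy and 103 infected TRGV3 molecules, 65 and 75 were joined to TRGJ2 and 35 and 10 to TRGJ4. TRGV3 shares and pairs here and below may thus hold TRGV1 or TRGV2 chains. TRGV4 fell from 16.1% ± 0.885 to 6.49% ± 0.864 with library totals as the scale (log2 −1.31), but its log2 change was 0.22 with TMM factors. TRGV7 went from 1.45% ± 0.571 to 0.702% ± 0.402 (log2 −1.15), a direction that turned with TMM (log2 0.38) and DESeq2 (log2 0.016), and TRGV5 took 0.622% ± 0.329 and 0.811% ± 0.144 (log2 0.37, and −0.14 by reads), which did not pass but did with TMM (log2 1.87), with DESeq2 (log2 1.58) and with the Vγ6 chain left out (log2 2.08). The log2 change of TRGV5 was 0.024 without healthy replicate 1 and 0.96 without healthy replicate 2. Of the J segments, TRGJ1, the partner of TRGV6, rose from 33.2% ± 0.775 to 82.5% ± 1.36 (log2 1.32) and TRGJ4 fell from 34.6% ± 0.957 to 7.02% ± 0.640 (log2 −2.29). TRGJ2 fell from 31.5% ± 1.79 to 10.1% ± 0.833 with library totals (log2 −1.63), against a log2 change of 0.089 with TMM, and TRGJ3 took 0.694% ± 0.328 and 0.321% ± 0.160 (log2 −0.91, turning to 0.76 with TMM and 0.22 with DESeq2). In edgeR's quasi-likelihood test 5 of 6 TRGV segments passed, 1 higher and 4 lower, as did 3 of 4 TRGJ segments, 1 higher and 2 lower, and 7 of 8 V-J pairs, 1 higher and 6 lower. With TMM these splits were 2 higher and 0 lower, 1 and 1, and 2 and 2, and with DESeq2 they were 2 and 2, 1 and 1, and 2 and 2. The share of one segment can only rise at the cost of the others, and the median log2 change over TRGV segments was −1.23 with library totals, 0.30 with TMM and −0.072 with DESeq2. The call of TRGV7 was lost without healthy replicate 1 (log2 −0.93), healthy replicate 2 (−1.08), infected replicate 2 (−0.84) or infected replicate 3 (−0.999), and also without clones of 1 molecule (−1.51), with nonproductive clones added (−0.79) and by reads (−0.78).

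The γ repertoire outside the Vγ6 chain also changed, with more TRGV4 and TRGV5 and less TRGV1. With the Vγ6 chain left out, a comparison chosen after the shares above were seen, TRGV4 rose from 18.7% ± 0.897 to 25.4% ± 1.74 of the remaining molecules (n = 3, log2 0.44, SE 0.07, adjusted p = 0.000948 by edgeR's quasi-likelihood test). The TRGV4 rise was carried by the chains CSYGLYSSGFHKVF (2.88 to 8.35%) and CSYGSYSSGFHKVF (1.24 to 3.38%). TRGV4 is the usual chain of another IL-17-making γδ subset. TRGV5 rose 4.42-fold from 0.720% ± 0.378 to 3.18% ± 0.525 (log2 2.08, SE 0.39, edgeR adjusted p = 0.00436), on 10 healthy and 47 infected molecules. The TRGV5 chain of epidermal γδ T cells, with the CDR3 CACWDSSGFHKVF, had 0 molecules in each infected library, so this rise lay in other TRGV5 chains. TRGV1 fell from 69.1% ± 2.26 to 60.9% ± 1.49 (log2 −0.19, SE 0.03, edgeR adjusted p = 0.0109). Each of these segment changes held in 3 of 3 infected libraries against every healthy one, and each kept its sign with TMM and DESeq2. TRGV3, TRGV6 and TRGV7 did not pass, with log2 changes of −0.20, −0.72 and 0.58. TRGJ1 rose from 22.6% ± 1.32 to 31.4% ± 1.93 of the remaining molecules (log2 0.49) and TRGJ4 fell from 40.1% ± 1.35 to 27.5% ± 0.465 (log2 −0.54), while TRGJ2 and TRGJ3 did not pass (log2 0.12 and 0.77). TRGV1 with TRGJ4 fell (log2 −0.50) and so did TRGV3 with TRGJ4 (log2 −1.88), the latter on 35 healthy and 10 infected molecules. TRGV1 with TRGJ4 went from 37.3 to 26.5%, while TRGV1 with TRGJ2 went from 31.7 to 34.3% and did not pass (log2 0.11). The lower TRGV1 share thus lay in chains with TRGJ4. The call of TRGV1 was lost with TMM (log2 −0.078), by reads (−0.13), and without healthy replicate 1 (−0.17) or infected replicate 1 (−0.17). The call of TRGV5 was lost by reads (log2 0.90), and that of TRGJ1 with TMM (0.36) and DESeq2 (0.35). With each clonotype counted once, TRGV4 had a log2 change of −0.24. Of the 6 TRGV segments tested 2 were higher and 1 lower, against 2 and 0 with TMM and 2 and 1 with DESeq2. Of the 4 TRGJ segments 1 was higher and 1 lower, against 0 and 1 with either. Of the 7 V-J pairs 2 were higher and 2 lower in all of these.

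**Figure D2:**
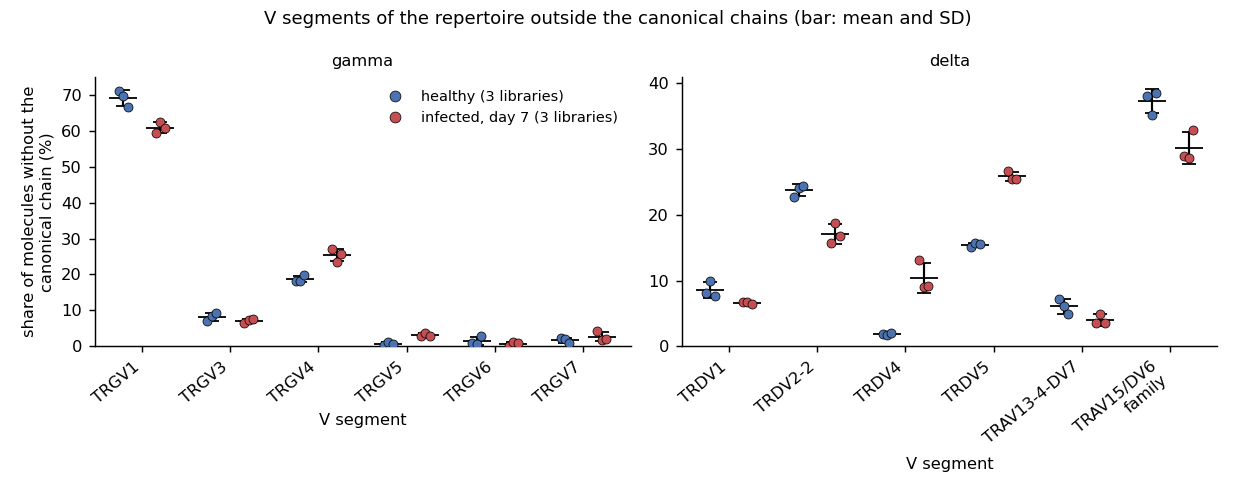
Share of molecules outside the canonical chain taken by each V segment (y axis, percent; γ and δ panels), with 1 point per library and bars for the mean and SD of 3 healthy and 3 infected libraries. TRGV4 went from 18.7 to 25.4%, TRDV5 from 15.4 to 25.8% and TRDV4 from 1.88 to 10.4%, each in the same direction with TMM and DESeq2 scaling.

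Among δ segments, TRDV4 rose, and 21 others fell with library totals as the scale, against 0 with TMM or DESeq2. TRDV4 went from 18.3% ± 2.395 to 89.0% ± 3.97 of δ molecules (n = 3, log2 2.28, edgeR adjusted p = 2.89e-22), and TRDJ2 from 17.3% ± 2.22 to 87.9% ± 4.16 (log2 2.35), each in 3 of 3 infected libraries. TRDJ1, the usual J segment of splenic δ chains, fell from 82.7% ± 2.22 to 12.1% ± 4.16 (log2 −2.78). TRDV2-2 fell from 19.7% ± 0.497 to 2.13% ± 0.942 (log2 −3.21) and TRDV1 from 7.14% ± 1.10 to 0.814% ± 0.303 (log2 −3.14). The segments of TRAV15 with DV6 and their copies TRAV15N-1 and TRAV15N-2, together the Vδ6 family used by NKT-like γδ cells with a Vγ1 chain, summed to 31.0% ± 1.32 and 3.64% ± 1.09 with library totals (log2 −3.09), against a log2 change of −0.030 with TMM and −0.060 with DESeq2. Its members TRAV15-1-DV6-1, TRAV15D-1-DV6D-1, TRAV15-2-DV6-2 and TRAV15D-2-DV6D-2 turned to log2 changes of 0.38, 0.061, 0.029 and 0.070 with TMM, while TRAV15N-1 and TRAV15N-2 stayed lower at −0.36 and −0.67 and did not pass. These near-identical copies are uncertain one by one, since 142 to 318 clones per library had several V segments listed. TRDV5 fell from 12.9% ± 0.358 to 3.15% ± 1.049 with library totals (log2 −2.03), and its log2 change was 1.07 with TMM and 0.98 with DESeq2. In edgeR's quasi-likelihood test 1 of 47 TRDV segments was higher and 21 were lower, and of 13 V-J pairs 1 was higher and 11 lower. With TMM the splits were 2 higher and 0 lower for segments and 3 and 1 for pairs, and with DESeq2 they were 2 and 0, and 3 and 0. The median log2 change over TRDV segments was −3.02 with library totals, 0.029 with TMM and −0.052 with DESeq2. TRDV4 and TRDV5 stood above the median on each scale. A change of scale shifts the segments by about the same amount, so the 3 scales are not separate evidence for this.

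Outside the Vδ1 chain, other TRDV4 chains and TRDV5 chains took a larger share of the δ repertoire after infection. TRDV4 without the canonical chain rose 5.54-fold, from 1.88% ± 0.116 to 10.4% ± 2.31 of the remaining molecules (n = 3, log2 2.47, SE 0.18, edgeR adjusted p = 1.47e-31), nearly all of it joined to TRDJ1 (1.75% ± 0.228 and 9.64% ± 2.41). TRDV5 rose from 15.4% ± 0.319 to 25.8% ± 0.718 (log2 0.74, SE 0.03, edgeR adjusted p = 1.91e-21). Joined to TRDJ1, TRDV4 had an edgeR adjusted p = 2.07e-05 (log2 2.46) and TRDV5 one of 9.56e-07 (log2 0.74) among V-J pairs. The size of these p-values thus depended on which features were tested together, and the exact permutation p was 0.1 for each segment. Both segments were higher in 3 of 3 infected libraries and kept their sign and call with TMM, DESeq2 and reads. TRDV2-2 fell from 23.7% ± 0.925 to 17.1% ± 1.57 (log2 −0.46), TRAV15N-1 from 6.88% ± 0.492 to 4.32% ± 0.601 (−0.69), TRAV13-4-DV7 from 6.07% ± 1.19 to 3.99% ± 0.858 (−0.58) and TRDV1 from 8.56% ± 1.18 to 6.62% ± 0.216 (−0.37). None of these 4 falls passed with TMM (log2 −0.18, −0.41, −0.31 and −0.091), with DESeq2 or by reads. The call of TRAV13-4-DV7 was also lost without healthy replicate 1 (log2 −0.43) or infected replicate 1 (−0.48), and that of TRDV1 without any 1 of the 6 libraries (log2 −0.43 to −0.25). The Vδ6 family made up 37.3% ± 1.79 and 30.1% ± 2.401 of the remaining molecules (log2 −0.32, edgeR adjusted p = 1.42e-05), in 3 of 3 infected libraries, but turned to log2 0.089 with TMM, was not past the threshold with DESeq2 (−0.067) and was lost without healthy replicate 3 (−0.29). TRDJ2 took 0.655% ± 0.155 and 1.22% ± 0.234 (log2 0.88, edgeR adjusted p = 0.0293), a call lost without healthy replicate 2 (0.93), healthy replicate 3 (0.73), infected replicate 2 (0.71) or infected replicate 3 (0.88), and also with DESeq2 (0.45), with the replicate block (0.86) and without clones of 1 molecule (0.93). Of the 47 TRDV segments 2 were higher and 4 lower, and of the 12 V-J pairs 2 and 5, against 2 and 0 for both with TMM and with DESeq2. The median log2 change over the 47 segments was −0.29 with library totals, −0.020 with TMM and −0.055 with DESeq2. The pair count dropped to 4 without healthy replicate 1. With each clonotype counted once TRDV5 no longer passed (log2 0.20), while TRDV4 did (log2 1.91).

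Single chains accounted for part of these shifts, and the rise of TRDV5 from 15.4 to 25.8% lay mostly in 1 of them. The Vδ5 chain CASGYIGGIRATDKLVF (TRDV5 with TRDJ1), known from IL-17-making Vγ4 cells, went from 0.481% ± 0.335 to 9.73% ± 0.854 of δ molecules outside the Vδ1 chain (n = 3), a 20.2-fold rise on 20 healthy and 310 infected molecules (log2 4.32, SE 0.57, edgeR adjusted p = 4.13e-05). Without healthy replicate 2, which held 12 of the 20 molecules, the log2 change was 5.03, and among all δ molecules 2.31. Its share of all δ molecules was 0.401% ± 0.283 and 1.198% ± 0.461 (log2 1.58, SE 0.64, edgeR adjusted p = 0.0235), with TMM turning this to log2 −0.73 and DESeq2 to −0.075 in a table of only 3 clonotypes. The TRDV4 chain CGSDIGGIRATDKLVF, which has TRDJ1 in place of TRDJ2, went from 0.803% ± 0.361 to 4.78% ± 1.69 of δ molecules outside the Vδ1 chain (log2 2.57, SE 0.46, edgeR adjusted p = 0.000529), with log2 changes of −0.65 under TMM and −1.03 under DESeq2 in a table of 2 clonotypes. Both chains were higher in 3 of 3 infected libraries with library totals, and neither passed when reads replaced molecules (log2 3.99 and 1.63), nor did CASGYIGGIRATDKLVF with TMM (log2 1.12). Of all δ molecules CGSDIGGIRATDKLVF took 0.664% ± 0.280 and 0.548% ± 0.112 (log2 −0.26), which passed with TMM (log2 −2.56), DESeq2 (−1.98) and without clones of 1 molecule (−1.48) and turned without healthy replicate 3 (0.098). The call of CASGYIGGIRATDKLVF among all δ molecules was lost without healthy replicate 1 (log2 1.19), healthy replicate 3 (1.46), infected replicate 1 (1.67) or infected replicate 2 (1.23), and also without clones of 1 molecule (0.47), with no filter (1.58) and by reads (2.36).

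Among γ chains outside the Vγ6 chain, the TRGV4 chain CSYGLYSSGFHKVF rose from 2.88% ± 0.601 to 8.35% ± 0.362 of molecules (n = 3, log2 1.56, SE 0.18, edgeR adjusted p = 4.31e-09), in 3 of 3 infected libraries. The TRGV4 chain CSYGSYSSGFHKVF rose from 1.24% ± 0.585 to 3.38% ± 0.577 (log2 1.46) and the TRGV1 chain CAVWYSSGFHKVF from 1.33% ± 0.0898 to 3.50% ± 1.59 (log2 1.35), each with an edgeR adjusted p = 0.00830. Both were lost with TMM (log2 0.87 and 0.76), DESeq2 (0.83 and 0.72), reads (1.49 and 0.89) and without clones of 1 molecule (1.197 and 1.15), and both fell below the count minimum without infected replicate 1, 2 or 3, which left 1 of the 3 calls. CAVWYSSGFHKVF was also lost without healthy replicate 1 (log2 1.40). Of all γ molecules, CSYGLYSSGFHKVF took 2.49% ± 0.539 in healthy and 2.13% ± 0.223 in infected libraries (log2 −0.18). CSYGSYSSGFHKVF took 1.07% ± 0.501 and 0.854% ± 0.0746 (log2 −0.27) and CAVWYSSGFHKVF 1.14% ± 0.0675 and 0.907% ± 0.476 (log2 −0.38), and none of these passed. Of all γ molecules, the TRGV1 chains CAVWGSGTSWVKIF and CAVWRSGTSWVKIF fell from 2.65% ± 0.544 to 0.473% ± 0.179 (log2 −2.41) and from 2.91% ± 0.594 to 0.598% ± 0.136 (log2 −2.26). Neither fall passed with the Vγ6 chain left out (log2 −0.68 and −0.52), and that of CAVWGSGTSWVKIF did not pass by reads (−1.75). The TRGV4 chain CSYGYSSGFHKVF fell from 1.51% ± 0.714 to 0.614% ± 0.168 of all γ molecules (log2 −1.28), but turned to log2 0.45 with the Vγ6 chain left out. Its call was lost without healthy replicate 2 (−0.94), healthy replicate 3 (−1.15) or infected replicate 2 (−1.05), and also with TMM (−0.53), DESeq2 (−0.49), the replicate block (−1.29), no filter (−1.28) and reads (−1.41). In edgeR's quasi-likelihood test 1 of 7 γ clonotypes was higher and 3 lower, against 1 and 2 with TMM and with DESeq2. Of 3 δ clonotypes 2 were higher and 0 lower, against 0 and 1 with TMM and 1 and 1 with DESeq2. Outside the canonical chains 3 of 6 γ clonotypes were higher and 0 lower (1 and 2 with TMM and with DESeq2), and 2 of 2 δ clonotypes were higher (0 calls with TMM, where 1 passed an unadjusted p under 0.05, and 1 higher and 1 lower with DESeq2). The median log2 change of the γ clonotypes was −0.38 with library totals, 0.37 with TMM and 0.42 with DESeq2.

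Chains of other cell types were not seen in these tables. Invariant NKT α chains, MAIT α chains, other rearrangements with an α J segment and immunoglobulin segments each had 0 of 6193 clones and 0 of 31726 molecules in the tables that could list α chains. The labels name only γ and δ chains as targets of the amplification, so these zeros say nothing on the purity of the sort, and no upper limit is given because clones under 4 reads were not listed. A TRGV5 chain with the same CDR3 as the Vγ6 chain, the canonical chain of epidermal γδ T cells, had 1, 2 and 1 molecules in the healthy libraries and 0 in each infected library.

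Diversity was lower after infection in both chains. At a common depth of 373 γ molecules, the number of clonotypes was 192 ± 3.04 (SD, n = 3) in healthy and 68.8 ± 5.22 in infected libraries, and the effective number from Shannon entropy was 108 ± 0.601 and 5.003 ± 0.672. At 1550 δ molecules the number of clonotypes was 1099 ± 82.6 and 159.5 ± 55.5, and the effective number 510.5 ± 94.6 and 2.71 ± 0.959. The inverse Simpson index was 37.8 ± 2.60 and 1.81 ± 0.114 for γ and 36.1 ± 9.03 and 1.30 ± 0.133 for δ. Clonality went from 0.110 ± 0.00372 to 0.623 ± 0.0256 for γ and from 0.111 ± 0.0189 to 0.812 ± 0.0515 for δ. The 10 largest clonotypes held 32.7% ± 1.049 and 82.9% ± 1.72 of γ molecules and 19.5% ± 2.54 and 90.3% ± 3.66 of δ molecules.

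The canonical chains did not account for all of this difference in diversity. With them left out, the effective number of clonotypes was 143.5 ± 4.99 in healthy and 110.9 ± 1.53 in infected libraries for γ at 324 molecules, and 686 ± 35.0 and 383 ± 40.5 for δ at 799 molecules. The number of clonotypes at these depths was 192 ± 3.66 and 169.8 ± 1.41 for γ and 718 ± 26.9 and 615 ± 17.5 for δ. The inverse Simpson index of the remaining δ repertoire was 628 ± 46.9 and 77.2 ± 14.6, and its 10 largest clonotypes held 4.09% ± 0.380 and 18.6% ± 2.56 of molecules. Every one of these measures separated the 3 healthy from the 3 infected libraries without overlap (two-sided exact permutation test, p = 0.1, the smallest possible), an outcome that chance gives in 10% of splits. Of δ molecules outside the Vδ1 chain, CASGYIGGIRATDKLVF took 0.481 and 9.73% and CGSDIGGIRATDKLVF 0.803 and 4.78% in healthy and infected libraries. Diversity with these chains left out as well was not measured.

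**Figure D3:**
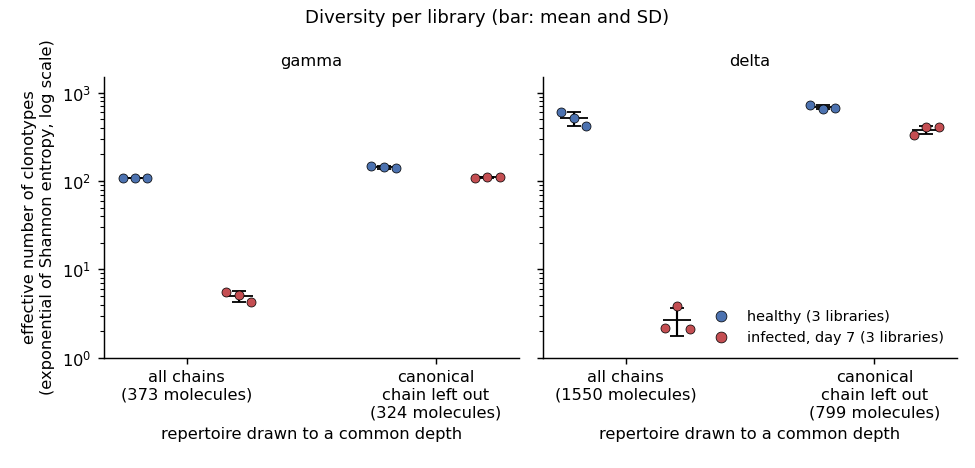
Effective number of clonotypes, the exponential of Shannon entropy (y axis, log scale), per library at a common number of molecules for all productive chains and with the canonical chain left out, with bars for the mean and SD of 3 healthy and 3 infected libraries. For δ the means were 510.5 and 2.71 with all chains and 686 and 383 without the canonical chain.

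Infected libraries resembled each other closely by an index that weights clonotypes by their abundance, and outside the canonical chains this rested largely on a few abundant clonotypes for δ. This Morisita-Horn index, which is 1 for equal clonotype shares and 0 for no shared clonotype, averaged 0.918 between pairs of healthy libraries, 0.999 between pairs of infected ones and 0.358 across groups for γ, and 0.960, 0.998 and 0.368 for δ. With the Vδ1 chain left out, healthy δ repertoires overlapped little (0.111 to 0.128), as did pairs across groups (0.0729 to 0.168), while pairs of infected libraries lay between 0.897 and 0.900. With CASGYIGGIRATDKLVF and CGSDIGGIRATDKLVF left out as well, infected δ pairs lay between 0.161 and 0.202 and healthy ones between 0.0426 and 0.0630. Without the Vγ6 chain the γ means were 0.709 within healthy, 0.854 within infected and 0.613 across groups, and with the 3 γ clonotypes called higher also left out they were 0.675, 0.690 and 0.617. The difference of within-group and across-group pairs had a one-sided exact permutation p = 0.1 with all chains, without the canonical chain and without the called clonotypes too, the smallest possible. The difference of infected and healthy pairs had a two-sided exact permutation p = 0.1 for γ and for both chains without the canonical chain, and p = 0.5 for δ with all chains. Without the called clonotypes too it had p = 0.6 for γ and p = 0.1 for δ (exact permutation). These clonotypes were picked for being higher in the same infected libraries, so leaving them out favours a lower index among infected pairs. The γ value thus does not decide whether the remaining chains were more alike after infection. By the Jaccard index, which ignores abundance, the γ overlap of infected minus healthy pairs was −0.0025 (exact permutation p = 0.8). Of the δ nucleotide clonotypes of the smaller library, pairs of infected libraries shared 4.41 to 5.24%, pairs of healthy ones 1.67 to 1.81% and pairs across groups 1.44 to 2.52%. These are values at full depth, which was not matched. The smaller library held 635 to 763 clonotypes in infected pairs, with 28 to 40 shared, and 1048 to 1140 in healthy ones, with 19 shared.

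**Figure D4:**
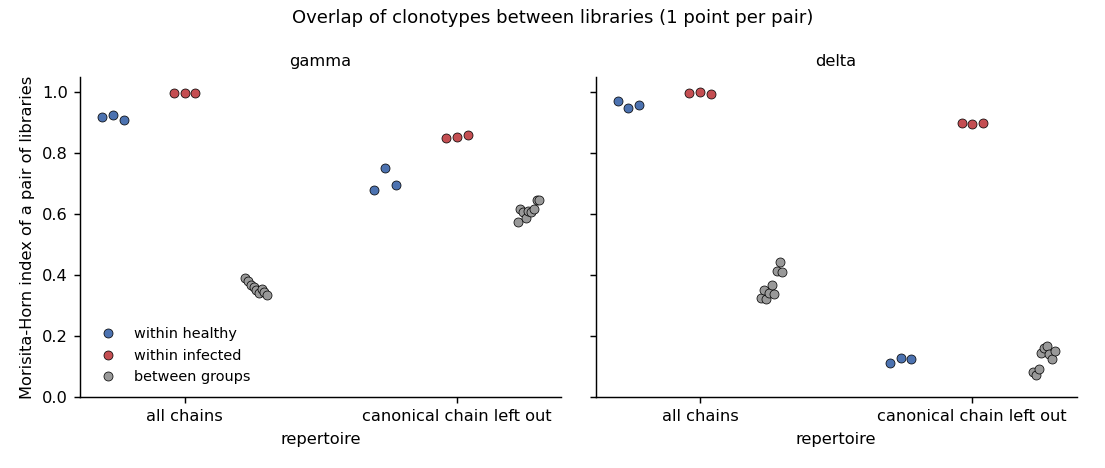
Morisita-Horn index of the clonotypes of each pair of libraries (y axis, 0 to 1), for pairs of healthy libraries, pairs of infected libraries and pairs across groups, with all chains and with the canonical chain left out. Without the Vδ1 chain, infected δ pairs lay at 0.897 to 0.900 and healthy ones at 0.111 to 0.128.

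CDR3 loops, the part of the chain that meets antigen, were shorter on average after infection. The mean length went from 13.8 ± 0.0468 to 13.2 ± 0.0199 amino acids for γ and from 17.9 ± 0.0324 to 17.1 ± 0.0463 for δ (n = 3, two-sided exact permutation p = 0.1 for each). Without the canonical chains it was 14.0 ± 0.0620 and 13.8 ± 0.0818 for γ and 18.0 ± 0.0482 and 17.6 ± 0.152 for δ (exact permutation p = 0.1 for each). Within single segments, TRGV1 loops went from 14.1 ± 0.0150 to 13.8 ± 0.111, TRDV5 loops from 17.8 ± 0.107 to 17.2 ± 0.185, TRAV13-4-DV7 loops from 16.1 ± 0.183 to 16.6 ± 0.280 and TRDV4 loops from 16.8 ± 0.0523 to 16.97 ± 0.0104 amino acids (exact permutation p = 0.1 for each). The TRDV4 values include the Vδ1 chain, and without it they were 14.7 ± 0.547 and 15.1 ± 0.152 (exact permutation p = 0.4). The other segments with a mean share of at least 1% had an exact permutation p of 0.2 or more.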

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

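All tests of explanations in this part were chosen only after the result they bear on was seen. Nonproductive γ chains, which the comparisons leave out, showed a pattern of their own. Chains without inserted bases made up 34.8% ± 1.70 (SD, n = 3) of nonproductive γ molecules in healthy libraries and 51.5% ± 6.41 in infected ones, on 239 and 575 molecules (two-sided exact permutation p = 0.1, the smallest possible). The rise lay mostly in 2 chains, which together made up 15.3% ± 1.68 and 31.3% ± 2.52, while all others without inserted bases made up 19.5% ± 2.13 and 20.3% ± 4.71 (exact permutation p = 0.9). The 2 were picked from these data as the nonproductive chains of TRGV1 with TRGJ2 that had the most molecules, 106 healthy and 350 infected. Leaving out chains picked this way favours a flat remainder, so this p does not decide whether the others rose. This drew attention because it is a signal in data outside the main measurement that lay above the level of the healthy libraries.

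Both chains join TRGV1 to TRGJ2, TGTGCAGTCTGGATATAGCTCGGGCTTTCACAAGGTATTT with 69 healthy and 207 infected molecules and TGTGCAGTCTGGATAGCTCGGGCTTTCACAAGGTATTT with 37 and 143. Error copies of the Vγ6 chain are argued against, since the closer of the pair is 5 single-base edits away from it. Nonproductive rearrangements that the Vγ6 cells carry beside the Vγ6 chain remain a candidate explanation. The pair gained 6.10 molecules per 100 Vγ6 molecules gained, but no chain is tied to a cell in these tables, so these cannot be told apart from chains of other cells.

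The second pattern is the larger share of the Vγ6 and Vδ1 chains after infection. Errors in the molecular identifiers of an abundant clone are argued against as the whole cause, because by reads the lowest infected share still lay 37.5 percentage points above the highest healthy one for γ and 49.1 points for δ. A mislabelled library is argued against by 0 libraries with a share within the range of the other group. As part of the cause such errors stay open, since infected shares by molecules were 14.6 points higher for γ and 16.2 points higher for δ than by reads. Reads per molecule of the canonical chain went from 32.6 ± 15.96 to 10.3 ± 1.69 for γ and from 17.6 ± 2.62 to 7.61 ± 1.12 for δ. An expansion or influx of Vγ6 Vδ1 cells in infection, or fewer other cells, stays open and untested. The molecules came from RNA, and receptor transcripts per cell were not measured, so shares of molecules cannot be read as shares of cells.

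The third pattern is that the Vδ1 chain took a larger share than the Vγ6 chain after infection, by 13.3 percentage points ± 4.61 (SD, n = 3) against 2.98 ± 3.03 in healthy libraries (exact permutation p = 0.1). By reads the gap changed sign, from −5.47 ± 3.84 points, where the Vγ6 chain had the larger share, to 11.8 ± 7.61. Inflated δ molecule counts are argued against as the whole cause, since the gap by reads was thus 17.3 points higher after infection and did not overlap between the groups. Chains listed under the neighbouring TRGV5 are argued against by its highest infected share, 0.970%, far below the lowest gap of 8.55 points. A further productive γ chain in the same cells could give a gap of 13.3 points, but chains are not paired in these tables, so this and a difference in amplification between the chains cannot be told apart.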

How the results depend on the processing

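All comparisons without the canonical chains, reads in place of molecules, and the scaling of the Vδ6 family were chosen only after the data were seen, and the other alternatives before. The rise of the Vγ6 chain kept its direction and call under every alternative run. That of the Vδ1 chain did so under every one but TMM, whose factors came from only the 3 δ clonotypes tested, this chain included. The differences in diversity and in mean CDR3 length over all segments kept their direction under every alternative run, in tests with no p under 0.1. At the depth of these libraries the test recovered 0% of 2-fold or 4-fold changes among the unfiltered δ clonotypes, where depth was not told apart from the number of tests. Over the items named one by one and their alternatives, 916 values kept direction and call, 244 lost the call, 7 gained one and 87 turned. Counting each clonotype once gave no value for clonotypes, since it leaves 1 count per clonotype, and no V-J pair or clonotype below a stricter minimum has a value there. For the changes below, those under TMM and DESeq2 included, the cause was not tested except where the alternative's construction is named.

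With TMM, 2 TRGV, 2 TRDV, 4 γ V-J pairs, 4 δ V-J pairs and 1 δ clonotype passed, and the Vδ1 chain had log2 0.074. Without the canonical chains TMM gave 2 TRDV, 1 TRGJ, 2 δ pairs and 0 of 2 δ clonotypes, of which 1 passed unadjusted. TMM turned TRGV4 to log2 0.22, TRGV7 to 0.38, TRGJ2 to 0.089 and TRGJ3 to 0.76. It turned TRDV5 to 1.07, TRAV13-2 to 0.50, TRAV14-3 to 0.42, TRAV3-4 to 0.24, TRAV15-1-DV6-1 to 0.38, TRAV15-2-DV6-2 to 0.029, TRAV15D-1-DV6D-1 to 0.061 and TRAV15D-2-DV6D-2 to 0.070. Among pairs with TRDJ1 it turned TRDV5 to 1.04, TRAV15-1-DV6-1 to 0.36, TRAV15-2-DV6-2 to 0.0068 (0.050 without the canonical chain), TRAV15D-1-DV6D-1 to 0.053 and TRAV15D-2-DV6D-2 to 0.050. It turned TRGV4 with TRGJ1 to 0.17, TRGV7 with TRGJ1 to 0.41, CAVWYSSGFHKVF to 0.37 and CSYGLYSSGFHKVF to 0.58. It turned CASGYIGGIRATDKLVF to −0.73, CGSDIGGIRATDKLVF without the canonical chain to −0.65, and the Vδ6 family without the canonical chain to 0.089.

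With DESeq2, 2 TRDV, 4 γ pairs and 3 δ pairs passed, and without the canonical chains 2 TRDV, 1 TRGJ, 0 of 2 TRDJ (0 unadjusted) and 2 δ pairs. DESeq2 turned TRGV7 to log2 0.016, TRGJ3 to 0.22, TRDV5 to 0.98, TRAV13-2 to 0.46, TRAV14-3 to 0.35, TRAV3-4 to 0.17, TRAV15-1-DV6-1 to 0.28 and TRAV15D-1-DV6D-1 to 0.038. Among pairs with TRDJ1 it turned TRDV5 to 0.97, TRAV15-1-DV6-1 to 0.28 and TRAV15D-1-DV6D-1 to 0.028. It turned TRGV4 with TRGJ1 to 0.22, TRGV7 with TRGJ1 to 0.46, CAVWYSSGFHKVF to 0.42, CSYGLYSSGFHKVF to 0.65, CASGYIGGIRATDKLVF to −0.075 and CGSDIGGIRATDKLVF without the canonical chain to −1.03.

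With each clonotype counted once, which removes the size of clones by construction, 0 of 6 TRGV, 0 of 4 TRGJ and 0 of 4 γ pairs passed edgeR's test (1, 1 and 0 unadjusted), with 1 TRDV, 1 TRDJ and 1 δ pair, and the counts were 0, 0 and 0 with 1 TRDV and 1 δ pair without the canonical chains. This turned TRGV3 to log2 0.18, TRGV6 to −0.25, TRGV7 to 0.74, TRGJ2 to 0.18, TRGJ3 to 0.94, TRGV1 with TRGJ2 to 0.069 and TRGV3 with TRGJ2 to 0.53. It turned TRDV5 to 0.20, TRAV13-2 to 0.70, TRAV14-3 to 0.40, TRAV3-4 to 0.56, TRAV15-1-DV6-1 to 0.37, TRAV15-2-DV6-2 to 0.011 and TRAV15D-1-DV6D-1 to 0.011. Among pairs with TRDJ1 it turned TRDV5 to 0.20, TRAV15-1-DV6-1 to 0.37, TRAV15-2-DV6-2 to 0.013 (0.014 without the canonical chain) and TRAV15D-1-DV6D-1 to 0.023. Without the canonical chain it turned TRGV4 to −0.24 and TRGV4 with TRGJ1 to −0.29.

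With the canonical chains left out of each table, 3 TRGV, 6 TRDV, 1 TRDJ, 4 γ pairs and 7 δ pairs passed. This turned TRGV4 to log2 0.44, TRGV6 to −0.72, TRGV7 to 0.58, TRGJ2 to 0.12, TRGJ3 to 0.77, TRGV1 with TRGJ2 to 0.11, TRGV3 with TRGJ2 to 0.096, TRGV4 with TRGJ1 to 0.43 and TRGV7 with TRGJ1 to 0.67. It turned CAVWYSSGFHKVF to 1.35, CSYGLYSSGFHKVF to 1.56, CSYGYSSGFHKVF to 0.45 and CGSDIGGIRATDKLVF to 2.57. It turned TRDV5 to 0.74 (0.74 with TRDJ1), TRAV13-2 to 0.19, TRAV14-3 to 0.11 and TRAV15-1-DV6-1 to 0.058 (0.056 with TRDJ1). The difference in TRGV6 CDR3 length turned to 0.989 amino acids.

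By reads, 13 TRDV and 1 δ clonotype passed, and without the canonical chains 1 TRGV, 2 TRDV, 2 δ pairs and 0 of 38 δ clonotypes (7 unadjusted). Reads turned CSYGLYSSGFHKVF to log2 0.73 and TRGV5 to −0.14. Without clones of 1 molecule 4 γ pairs passed, and without the canonical chains 0 TRDJ (0 unadjusted), 2 γ pairs and 1 γ clonotype, and TRGJ3 turned to 2.05. With no filter 24 δ pairs, 9 γ clonotypes and 1 δ clonotype passed, with a minimum of 50 molecules 4 γ pairs and 1 γ clonotype, and with CDR3 nucleotides 2 γ clonotypes. By the Jaccard index the γ overlap within infected minus within healthy libraries turned to −0.0025. Leaving out 1 library gave 1 to 2 δ clonotypes and, without the canonical chains, 4 to 7 δ pairs, 0 to 1 TRDJ and 1 to 3 γ clonotypes. For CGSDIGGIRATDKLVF the log2 change ranged from −0.50 to 0.098, the turn being without healthy replicate 3.

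Replicate numbers run from 1 to 3 in each group, but mice with the same number did not deviate together over 21 V-J pairs (correlations −0.23, −0.16 and 0.021), so the numbers were not taken to pair the mice. With the replicate number as a block, 0 of 2 TRDJ segments passed without the canonical chain (1 unadjusted), and no other count moved by over 1.5 times. With 3 pairs the sign-flip tests of diversity and CDR3 length give no p under 0.25.

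The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of the 10, gave as many calls as it did in each table. The real split and the highest of the others gave 5 and 1 for TRGV, 22 and 0 for TRDV, 3 and 0 for TRGJ, 2 and 0 for TRDJ, 7 and 0 for γ pairs, 12 and 0 for δ pairs, 4 and 0 for γ clonotypes and 2 and 0 for δ clonotypes. Without the canonical chains they gave 3 and 0, 6 and 1, 2 and 1, 1 and 0, 4 and 0, 7 and 0, 3 and 0, and 2 and 0 in the same order.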

Other observations

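The tests of explanations in this part were chosen only after related values were seen. Around the Vδ5 chain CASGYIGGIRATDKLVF, chains that differ from it in 1 residue were also more common after infection. They took 0.514% ± 0.249 (SD, n = 3) of δ molecules outside the Vδ1 chain in healthy libraries and 3.06% ± 0.815 in infected ones, on 21 and 93 molecules (two-sided exact permutation p = 0.1, the smallest possible). These were 16 distinct chains in healthy and 27 in infected libraries. Chains with TRDV2-2 that end in the same residues, GGIRATDKLVF, took 3.08% ± 0.212 and 1.65% ± 0.750 (exact permutation p = 0.1), the opposite direction.

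Nonproductive chains took a smaller share of γ molecules after infection, as did δ ones, while their number of γ molecules per library was higher, 230.3 ± 46.1 in healthy and 369 ± 82.4 in infected libraries (exact permutation p = 0.1). Productive molecules other than the canonical chains carried on average 24.4 ± 4.78 and 20.3 ± 4.21 reads for γ (exact permutation p = 0.4) and 27.2 ± 4.14 and 22.0 ± 4.35 reads for δ (exact permutation p = 0.2).

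One hypothesis is that chains close to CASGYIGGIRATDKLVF rose together with it. Its neighbours met this at 3.06%, but this is the value already given above, so it is no separate test. The neighbours may also hold copies of the main chain with an amplification or sequencing error, which was not tested. Whether the shared ending goes with the rise stays open. The TRDV2-2 chains with it fell to 1.65%, while the TRDV4 chain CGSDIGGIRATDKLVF, which also has it, rose to 4.78% with library totals as the scale (log2 2.57). TMM (log2 −0.65) and DESeq2 (−1.03) cannot decide this rise, since their factors came from only 2 clonotypes, this chain and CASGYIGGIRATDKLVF.

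A further hypothesis is that chains made without inserted bases, the kind common in fetal life, may have risen as a class outside the Vγ6 chain. Such chains took 20.5% ± 2.07 of the remaining productive γ molecules in healthy libraries and 31.9% ± 2.26 in infected ones, on 272 and 458 molecules (n = 3, exact permutation p = 0.1), in 3 of 3 infected libraries. Part of this lay in 3 clonotypes called higher, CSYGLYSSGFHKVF, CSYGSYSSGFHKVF and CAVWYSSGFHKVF, whose chains without inserted bases took 3.90% ± 0.402 and 11.4% ± 1.204. All others took 16.6% ± 2.07 and 20.4% ± 2.61, but since the 3 were picked for being higher, this does not decide whether the whole class rose, which stays open. Such chains can also form in adult life, and the time at which a chain was made was not measured.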
